A study of Drosophila melanogaster with 3 samples.

How the data were processed

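The series comprised 3 two-colour Agilent tiling arrays of BG3 cells, 1 per DNA extraction, each with both channels from the same cell line. Per the labels' protocols, DNA of early-activating origins was labelled with BrdU, enriched with an anti-BrdU antibody and labelled with Cy3 or Cy5 dUTP. Which channel held BrdU-labelled DNA, and what the other channel held, is not given in the sources used here. The arrays were placed in 1 group by their titles, which number the extractions.

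The following kinds of deposited file were used. The scanner files hold, per the file headers, the intensity of each spot from Agilent Feature Extraction 9.5.1.1: mean and local background signals, processed signals (background-subtracted and dye-normalized by that software), outlier and background flags, and a log10 ratio of Cy5 over Cy3, which was only used to check the processed signals. The authors deposited normalized log2 ratios made with MA2C, per the name of the files; these have an SD of 1 on each array and medians of -0.03, 0.16 and 0.13, so they are treated as a score in SD units and were centred on their medians here. MA2C settings are not given in the sources used here. The deposited peak list holds 433 origins with 1 score each, capped at 3000, called for the series as a whole; its header names FlyBase release 5.3, and the probes were designed on release 5.1, per the file headers. Both are release 5, and coordinates are printed as the files give them. The score's scale is unknown.

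The main ratio was the log2 of processed Cy5 over processed Cy3, turned to a common direction, without control spots or outlier-flagged probes (892, 44 and 33 flagged on replicates 1, 2 and 3), and centred on each array's median, with no loess. Median mean signals were 175 (Cy3) and 142 (Cy5) on replicate 1, 657 and 452 on replicate 2, and 125 and 250 on replicate 3, and median signal over local background ranged from 2.03 to 19.0. Direction had been planned as channel 1 over channel 2 by the labelled dyes with 1 sign common to the arrays. That sign was set so that probes in deposited origins had the higher mean, which gave channel 2 over channel 1. Turned so, replicate 2 correlated negatively with the others, so the direction of each array was instead taken from the sign of its correlation with the authors' deposited values (Cy5 on replicates 1 and 2, Cy3 on replicate 3); this departure was decided after seeing those correlations, and the planned direction was kept as an alternative. Replicates 2 and 3 have 1 labelled orientation yet correlate below 0. This argues against the numbered channels holding the same DNA on all 3 arrays. The labels do not name the BrdU channel and so leave the direction unsettled. Values turned by channel number are therefore given beside comparisons of windows, arms, origins and named regions.

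Probes were averaged in 10 kb windows with at least 5 probes (12094 windows, of which 11714 on 2L, 2R, 3L, 3R, 4 and X). Window means were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg 0.05). On simulated data for the 12094 windows, the fit recovered 8% of windows changed by a log2 ratio of 0.5, 88% at 1 and 100% at 2 and at 4, with 3 false calls among 151; the simulation gave each array the same size of change, which the real arrays did not show. Arms were compared by rotating window values along the genome over every possible offset (smallest p 8.5e-05); of 500 simulated series without a difference, 4.6% had p under 0.05. X covers a large part of the rotated genome, so few rotations are independent. Origins per arm were compared with exact binomial tests and with the same rotation, spacing with 10000 random placements within arms, and origin medians with 100000 permutations. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures in matplotlib 3.10.9.

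The alternatives fixed before the data were examined were the deposited normalized values, normexp background correction with an offset of 50, probes well above background only, windows of 5 and 20 kb, at least 3 probes per window, a dye term, eBayes with trend and robust, origins with a score at or above the median, expected shares by probes, and leaving out each array. Added after seeing the data were the dyes as labelled, adjustment for GC content in bins of 1 percentage point, the deposited values without centring, the deposited values turned by the labelled dyes, centring on probes outside origins, scaling the arrays to equal SD, and normexp without an offset. Both normexp settings started from mean and local background signals, not from processed signals. They therefore also left out the scanner software's dye normalization and were only centred on each array's median.

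Named regions followed a rule fixed before the data were examined as far as it could be applied: the 10 origins with the highest score, and the 12 highest and 12 lowest items past an adjusted p of 0.05 with 1 sign on all arrays, at least 100 kb apart. The rule had been written for genes and was applied to windows; using the fit to the deposited values for it, and breaking ties at the score's limit by width, were chosen after seeing the data, as were the comparison of X with autosomal origins, the distance profile and the origin-free stretches. The gene table used for naming is of release 6 and the scanner files name probes by position only, so genes were not placed: counts of genes, fixed gene lists, gene density and origins at gene starts were not analysed here.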

Results

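Early replication origins were mapped in ML-DmBG3-c2 (BG3), a Drosophila melanogaster cell line derived from the central nervous system, whose sex the labels give as unknown. Origins that start DNA synthesis before the intra-S phase checkpoint halts further firing were marked with the thymidine analogue BrdU, and BrdU-labelled DNA was enriched with an antibody and hybridised to 2-colour tiling arrays. The series held 1 group of 3 arrays from 3 separate DNA extractions (replicates 1 to 3). The comparison was between the 2 channels of each array, and the question was where in the genome early-firing origins lie. Each array carried 241469 probes, with a median distance of 470 bp between neighbouring probes on the main chromosome arms. Both dyes were well above background at 93.1% of probes on replicate 1, 99.9% on replicate 2 and 99.7% on replicate 3. Nothing in the labels says whether the extractions came from separate cultures. The p-values of the window fits therefore measure only the spread between these 3 extractions, and their number limits the precision. The p-values from rotations, random placements, origin counts and permutations of origins do not measure the spread between arrays.

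The labels gave the dye of each numbered channel but not the channel that held BrdU-labelled DNA. When the ratios were turned by channel number, replicate 2 ran against the others over probes, with a Pearson r of -0.42 to replicate 1 and -0.64 to replicate 3, while replicates 1 and 3 had an r of 0.63. Direction was therefore not settled by the labels. It was taken for each array from the authors' deposited normalized values and is only likely: "higher" below means toward the channel those values treat as enriched, and turning all arrays would swap higher and lower. Turned this way, the 3 arrays correlated at r of 0.72 (replicates 1 and 2), 0.89 (1 and 3) and 0.87 (2 and 3) over 12094 windows of 10 kb, which are not independent of each other. Turned by channel number instead, the mean r over pairs was -0.23. A log2 ratio of 0 is the array's median probe and does not mean that a region was not replicated.

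Signal was concentrated in the 433 early origins of the authors' deposited peak list. These origins had a median width of 27.4 kb, from 10.045 to 171.8 kb, and covered 15.5 Mb in total. Probes inside them had a mean log2 ratio higher than probes outside by 1.23 on replicate 1, 0.26 on replicate 2 and 0.99 on replicate 3, a mean of 0.83 ± 0.51 (SD, n = 3), or 1.78-fold. Of the 433 origins, 424 had a mean above 0 on all 3 arrays. On replicate 2, 426 were above 0, and by channel number those lie below 0 on that array. The sign of this difference follows from how direction was set, and its size is not independent of the list, because the peaks were called on these arrays, so no p-value was computed. With normexp background correction the difference was 0.26 ± 0.14 (SD, n = 3), and turned by channel number it was 0.66 ± 0.80.

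Across the edges of wide origins the signal fell gradually. Because only wide origins reach far inside their edges, the profile was taken around the 133 origins over 40 kb on the main arms; wider ones among them still give more of the innermost probes, and the edges were called on these same arrays, so the profile describes the list and was not tested. Probes more than 20 kb inside an edge had a mean log2 ratio of 1.23 ± 0.67 (SD, n = 3), and those within 5 kb inside the edge had 0.36 ± 0.26. Within 5 kb outside the edge the mean was 0.20 ± 0.18, at 10 to 20 kb outside it was 0.04 ± 0.03, and beyond 100 kb it was -0.08 ± 0.07. In the channel-number direction, the same means were 0.92 ± 1.20, 0.31 ± 0.36, 0.18 ± 0.20, 0.03 ± 0.04 and -0.07 ± 0.09. The range was smaller on replicate 2, whose log2 ratios had an SD of 0.25 over probes against 0.75 on replicate 1 and 0.52 on replicate 3.

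**Figure D1:**
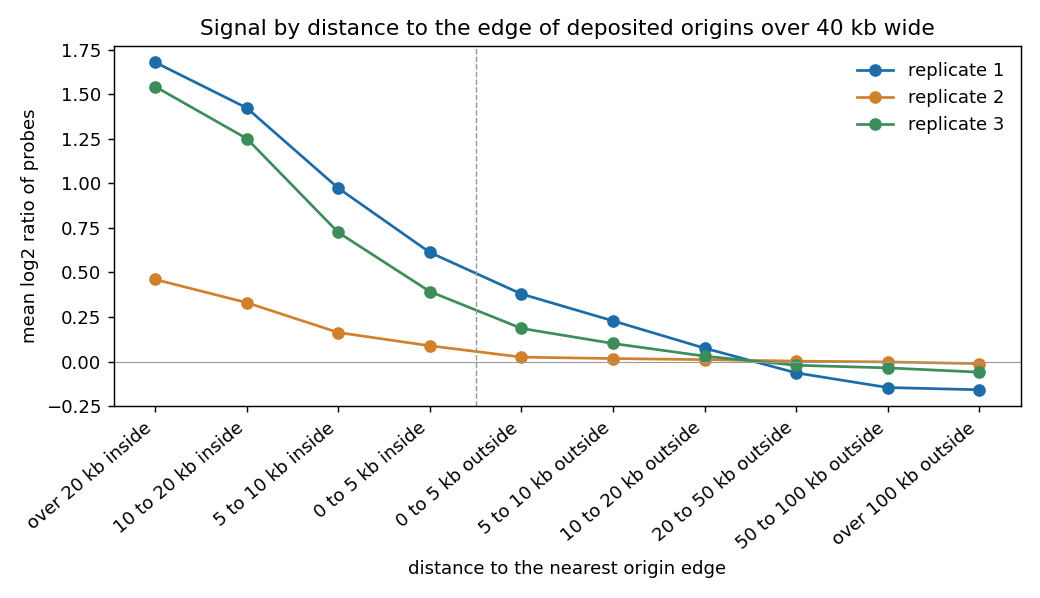
Mean log2 ratio of probes (vertical axis, 0 is the array's median) by distance to the nearest edge of a deposited origin (horizontal axis), for the 133 origins over 40 kb wide, with 1 line per array and the edge dashed. All 3 lines fall across edges that were called on these arrays, from 1.68, 0.46 and 1.54 more than 20 kb inside on replicates 1, 2 and 3.

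The 10 origins with the highest deposited score, all at the score's upper limit of 3000 and ranked by width among the 16 at that limit, lay on X (7 origins), 3R (2) and 3L (1). Positions are in FlyBase release 5 coordinates. The widest were on X from 3545111 to 3688466, with a mean log2 ratio of 1.22 ± 0.71 (SD, n = 3), and on X from 3222121 to 3365271, with 1.31 ± 0.76. An X origin from 12539871 to 12674913 had 1.17 ± 0.58. The highest mean among the 10 was 1.65 ± 0.78 on 3R from 11787971 to 11877308, followed by 1.499 ± 0.74 on 3L from 8635171 to 8717605 and 1.43 ± 0.71 on 3R from 25066811 to 25147295. The remaining X origins, starting at 19020671, 5756851, 13152811 and 6696281, had mean log2 ratios of 1.004 ± 0.50, 1.15 ± 0.66, 1.099 ± 0.56 and 1.01 ± 0.44. All 10 were above 0 on each array, and in each the SD came mainly from the lower values of replicate 2. By channel number, their means lay between 0.68 ± 1.02 and 1.15 ± 1.64, again highest for the 3R origin from 11787971, and all 10 lay below 0 on replicate 2. The score is the authors' own and its scale was not given in the sources used here.

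**Figure D2:**
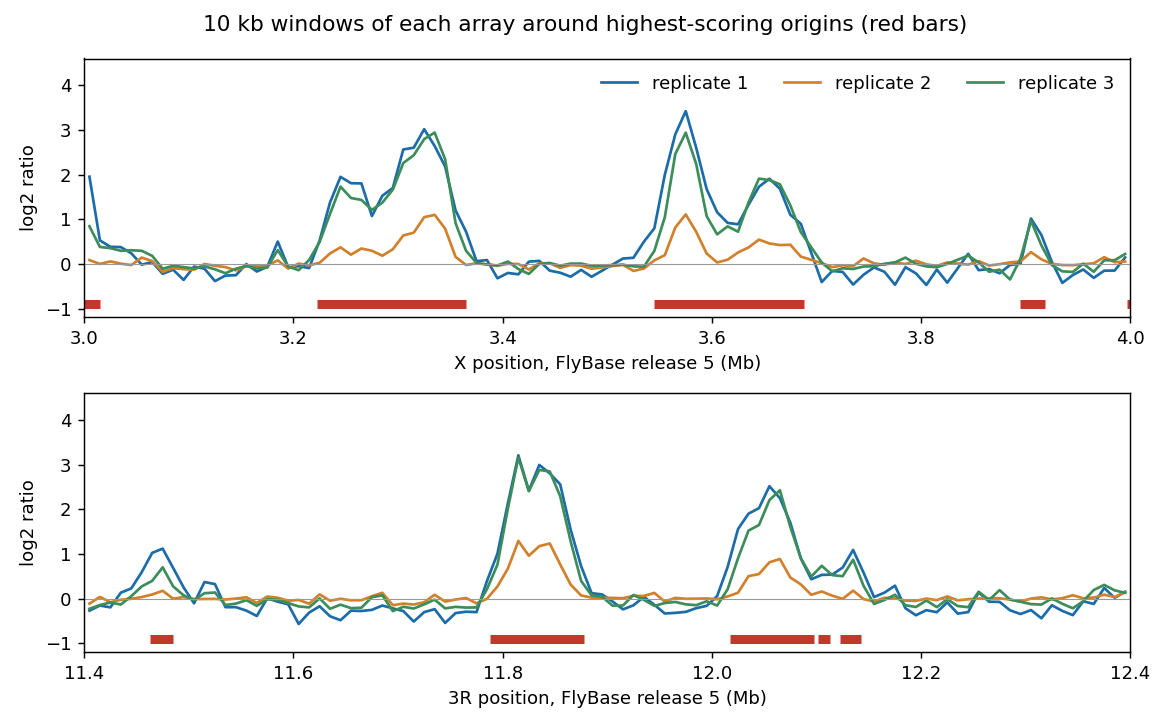
Log2 ratio in 10 kb windows of each array (coloured lines) along 1 Mb of X and 1 Mb of 3R in release 5 coordinates, with deposited origins as red bars. The arrays peak at the same places, with replicate 2 lower than the others at every high peak.

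Among the 6 main arms, early origins were most frequent, per length, on chromosome 4 and X. The X held 151 origins against 77.6 expected from its share of windows, or 6.97 per Mb, and chromosome 4 held 12 against 4.37, or 9.84 per Mb. Arm 2L held 49 against 79.9 (2.19 per Mb) and 3R held 65 against 99.3 (2.34 per Mb). Arms 2R and 3L held 76 against 73.1 and 77 against 85.1. By exact binomial tests (two-sided, Benjamini-Hochberg over chromosomes) the excess on X (adjusted p = 6.4e-16) and chromosome 4 (adjusted p = 0.0058) and the deficits on 2L and 3R (adjusted p = 3.0e-04 for each) passed 0.05, while 2R (adjusted p = 0.83) and 3L (adjusted p = 0.57) did not. Expected counts share out all origins, so the excess on X by itself lowers the ratios of the other arms. The deficits on 2L and 3R were not tested apart from it. With only origins scored at or above the median, the same binomial test no longer passed for 2L (adjusted p = 0.38) and chromosome 4 (adjusted p = 0.10). It still passed for X (adjusted p = 2.2e-04), where the ratio of observed to expected was 1.67 against 1.95 with all origins. X was also higher than the large autosomal arms outside origins, by 0.18, 0.04 and 0.09 on replicates 1, 2 and 3. Because peaks were called on these arrays, that higher level may have added X origins to the list, which was not tested. The binomial test treats origins as independent, and origins lay closer to their neighbours than randomly placed ones, with a median distance of 151 kb against 171 kb (95% of random placements 157 to 186 kb, permutation p = 0.0031), although the coefficient of variation of these distances, 1.15, lay within the range of random placements (0.96 to 1.17, permutation p = 0.090). Rotating the origin counts along the genome, which keeps any clustering, gave a permutation p = 0.035 for X, 0.034 for chromosome 4, 0.25 for 2L and 0.24 for 3R, which became 0.10 for X and chromosome 4 and 0.38 for 2L and 3R when adjusted over the 6 arms, so none of the 4 passed 0.05 by that test.

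**Figure D3:**
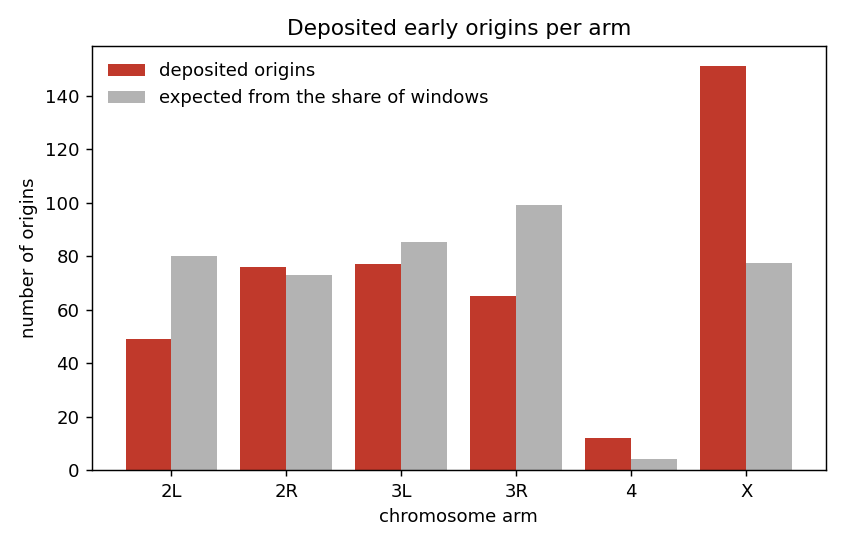
Number of deposited early origins per chromosome arm (red bars) beside the number expected from the arm's share of 10 kb windows (grey bars). X has 151 against 77.6, and chromosome 4 has 12 against 4.37.

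Origins on X had a lower median signal than those on the large autosomal arms 2L, 2R, 3L and 3R in the processed signals, a difference of the opposite sign with normexp. The median log2 ratio was 0.48 over 151 X origins and 0.62 over 267 autosomal origins (two-sided permutation test of medians, p = 1e-05, the smallest that 100000 resamples can give). The difference was present on replicate 1 (0.70 against 1.002, adjusted p = 2e-05) and replicate 3 (0.60 against 0.76, adjusted p = 2e-05) but not on replicate 2 (0.18 against 0.17, adjusted p = 0.13). The median deposited score was also lower on X, at 54.6 against 81.7 (adjusted p = 0.037), and widths of 29.8 and 27.1 kb did not differ past the threshold (adjusted p = 0.17). Adjusted values are over 6 measures, and the test treats origins as independent. The origins were also called on these same arrays, and X was higher outside origins by 0.18, 0.04 and 0.09 on replicates 1, 2 and 3. Weaker X regions may therefore have entered the list and lowered the X medians. These p-values thus describe the listed origins and cannot separate such selection from a difference in origin strength. X minus autosomal origins was -0.14 in the processed signals, -0.08 SD units in the deposited normalized values (permutation p = 0.20) and 0.14 with normexp, so no direction held across these settings. With normexp the medians were 0.18 on X and 0.04 on autosomes, and the mean r between arrays over windows was 0.56. Turned by channel number the difference was -0.15. In the direction used here it was -0.07 without replicate 1 and -0.23 without replicate 2.

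The whole X also had a higher mean window log2 ratio than the large autosomal arms. The difference was 0.31 on replicate 1, 0.07 on replicate 2 and 0.23 on replicate 3, a mean of 0.21 ± 0.12 (SD, n = 3), positive on 3 of 3 arrays. A permutation test by rotation of the array mean along the genome gave p = 0.045 (two-sided), which became 0.135 when adjusted over the 6 arms and so fails the correction. An exact sign-flip test over 3 arrays cannot go below 0.25 and gave that value. In the authors' deposited normalized values the difference was 0.54 ± 0.05 in units of each array's SD, with an adjusted p of 0.048, and over all 11 alternatives the adjusted p lay between 5.1e-04 and 0.15. Turned by channel number the mean difference was 0.16 ± 0.20 (permutation by rotation, p = 0.046), and replicate 2 lay below 0.

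Chromosome 4 was higher than the large autosomal arms on replicate 1 by 0.75 and on replicate 3 by 0.45 but not on replicate 2, where the difference was -0.02. The mean was 0.39 ± 0.39 (SD, n = 3), with a permutation p by rotation of 0.0069 and an adjusted p of 0.041 over the 6 arms, higher on 2 of 3 arrays. The rotation used the mean over arrays, so its p-value leaves out the disagreement between them. In the deposited normalized values the difference was 0.47 ± 0.62 SD units (adjusted p = 0.34), and with normexp background correction it was -0.02 ± 0.22, so it was not found under that setting. Without replicate 1 it was 0.21 (adjusted p = 0.15). Over the 11 alternatives the adjusted p ranged from 0.0031 to 0.99. Turned by channel number the value was 0.41 ± 0.37. Over the 122 windows of the chromosome the arrays correlated at r of 0.67 (replicates 1 and 2), 0.78 (1 and 3) and 0.94 (2 and 3), and by channel number at -0.67, 0.78 and -0.94. The window from 420001 to 430000, 1 of the 12 highest windows at least 100 kb apart, had a log2 ratio of 2.34 ± 1.26 (SD, n = 3), or 1.72 ± 2.32 by channel number. Arms 2L, 2R, 3L and 3R each lay within 0.04 of the mean of the others, with rotation p-values from 0.69 to 0.96.

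**Figure D4:**
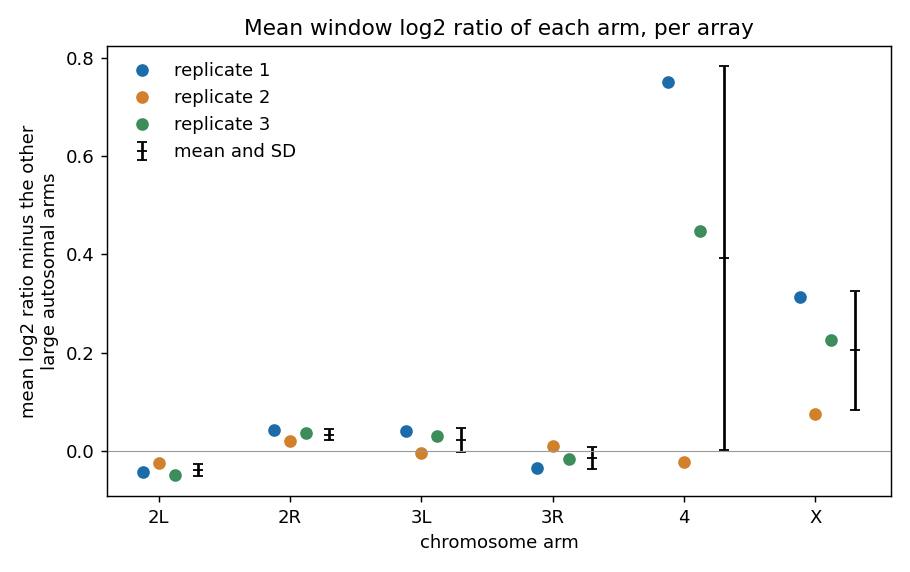
Mean log2 ratio over the 10 kb windows of each arm minus that of the other large autosomal arms (2L, 2R, 3L and 3R), with 1 point per array and the mean with its SD beside them. In the direction taken from the deposited values, X lies above 0 on all 3 arrays, and chromosome 4 does so on replicates 1 and 3 but not on replicate 2, at -0.02.

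No single 10 kb window passed the test over the 3 arrays. With limma on processed signals, 0 of 12094 windows had a Benjamini-Hochberg adjusted p under 0.05, the lowest being 0.204, although 2428 windows had an unadjusted p under 0.05. The window with the lowest p, on X from 12640001 to 12650000, had log2 ratios of 3.10, 1.41 and 3.08. In the direction used here, 7274 windows (60.1%) had 1 sign on all 3 arrays, against 25% if signs were independent. Of 18 alternatives, 8 made calls and 10 made none. Leaving out replicate 2 gave 2899 windows, leaving out replicate 3 gave 276 and leaving out replicate 1 gave 0. Scaling the processed signals to equal SD on each array, added after seeing the data, gave 2216 (1731 higher and 485 lower). The authors' deposited normalized values, which are scaled to equal SD on each array, gave 2003 windows (1426 higher and 577 lower). Without centring they gave 1807 higher and 168 lower, and normexp background correction gave 343 higher and 1083 lower, so the balance of higher and lower calls was not settled. Turned by channel number, the processed signals gave 0 (30 at an unadjusted p under 0.05) and the deposited values gave 0 (93). Replicate 2 then opposes the other arrays and cancels part of their mean, so few calls were possible and these counts carry little weight.

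The windows named here come from the fit to the deposited normalized values, a choice made after the fit to processed signals had called none. Of its 1426 higher windows, 1256 held probes of a deposited origin, and 0 of its 577 lower windows did, while 1905 of all 12094 windows held such probes. Peaks were called on these same arrays, so the overlap of called windows with origins follows from how the list was made and was not tested. The higher calls were unevenly spread: 31.8% of X windows were higher and 0.23% lower, against 6.4% higher and 7.1% lower on 2L, 9.4% and 2.7% on 2R, 8.0% and 9.2% on 3L, 6.7% and 4.4% on 3R, and 10.7% and 0.82% on chromosome 4. The 12 highest windows, at least 100 kb apart, all lay entirely inside deposited origins and had log2 ratios of 2.34 to 2.97 in the processed signals (adjusted p from 0.0026 to 0.0029 in the deposited values). They included windows on 3R from 11810001 to 11820000, at 2.56 ± 1.09 (SD, n = 3), on X from 12640001 to 12650000, at 2.53 ± 0.97, and on 3L from 3240001 to 3250000, at 2.51 ± 1.104. The highest was in unplaced sequence (U) from 5300001 to 5310000, at 2.97 ± 1.37, and rested on 7 probes. The 12 lowest windows reached log2 ratios of only -0.36 to -0.42 (adjusted p from 0.0041 to 0.047), all outside origins. Among them were 3L from 410001 to 420000, at -0.39 ± 0.36, and 3L from 2280001 to 2290000, at -0.37 ± 0.31. In the direction of the channel numbers, the 12 highest windows had means of 1.502 to 2.004 and the 12 lowest -0.26 to -0.34, and with the deposited values turned this way no arm had a called window.

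**Figure D5:**
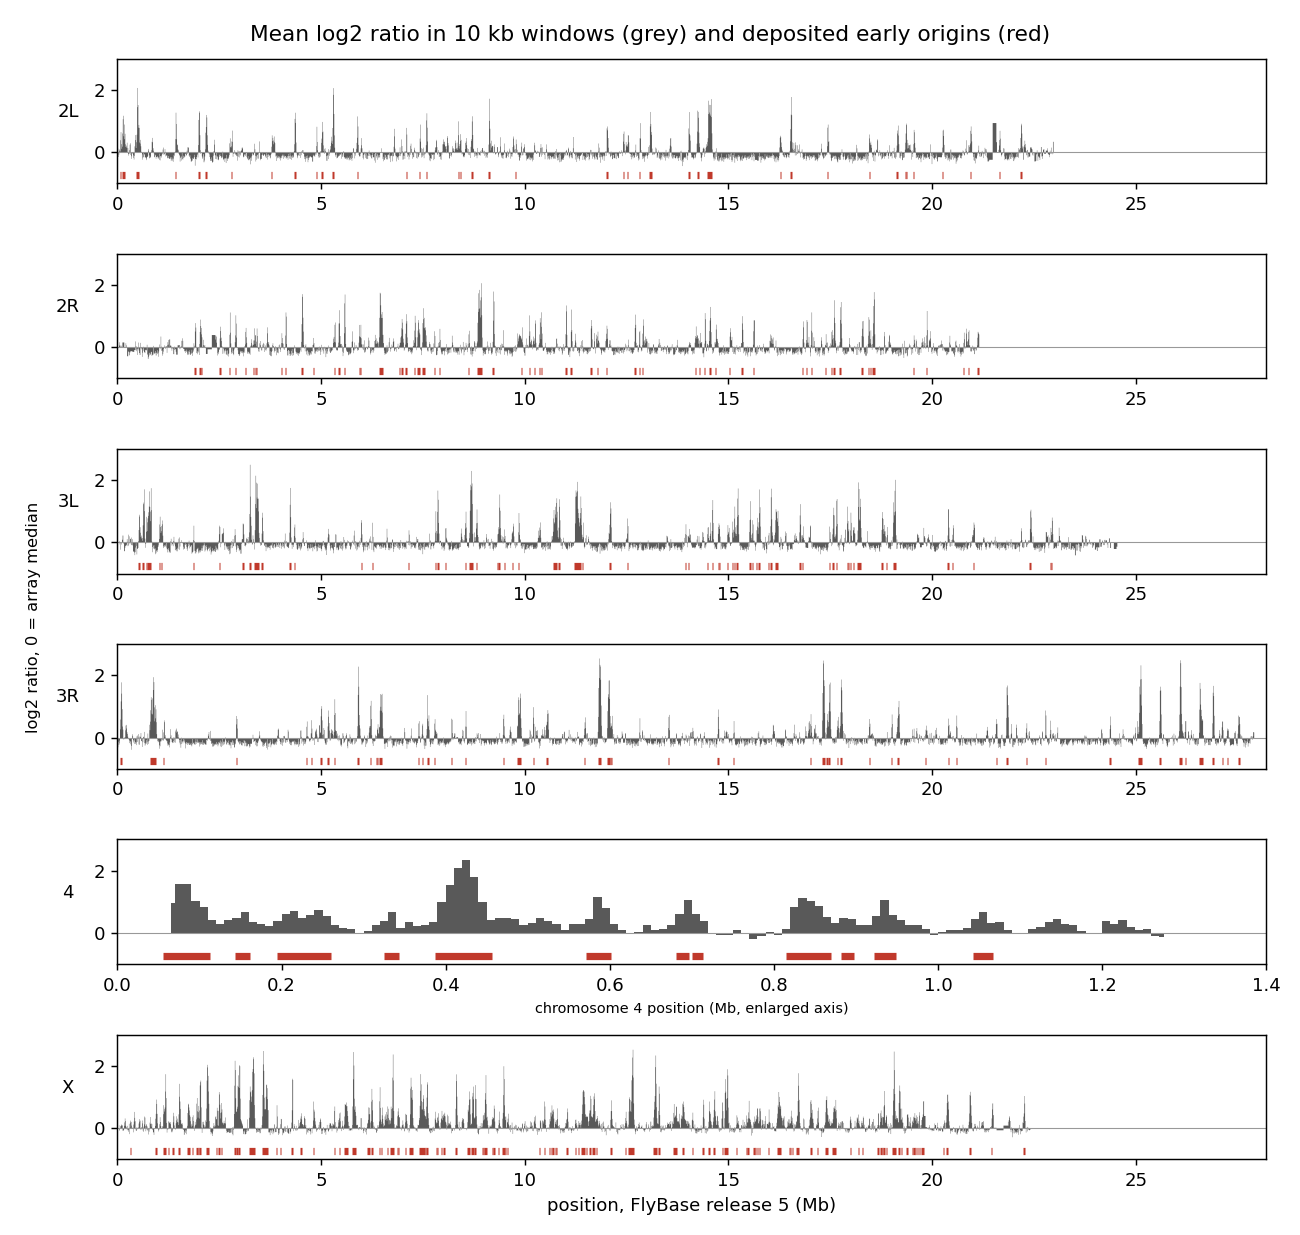
Mean log2 ratio over the 3 arrays in 10 kb windows (grey) along each arm in release 5 coordinates, with deposited origins as red marks; chromosome 4 has an enlarged axis. High windows coincide with deposited origins, which were called on these same arrays. Origins are denser on X (6.97 per Mb) and chromosome 4 (9.84 per Mb) than on the other arms.

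Long stretches held no deposited origin. The longest was on 2L from 9786357 to 11995270, 2.21 Mb with a mean log2 ratio of -0.08 ± 0.06 (SD, n = 3), followed by 3R from 1151948 to 2900200 (1.75 Mb, -0.12 ± 0.09) and 3R from 2929856 to 4631560 (1.70 Mb, -0.12 ± 0.10). The longest such stretch on X, from 9591671 to 10357640, was 0.77 Mb and had a mean of 0.03 ± 0.004. With the ratios turned by channel number, the 3 longest stretches had means of -0.07, -0.11 and -0.10, and that of X 0.007. These stretches were not tested.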

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

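Turning by the labelled dyes was the planned direction and became an alternative after the data were seen; GC adjustment, deposited values without centring, centring outside origins, equal SD and normexp without an offset, and all tests of X against autosomal origins, were chosen after the data were seen. The count of windows past the threshold, 0 with limma on processed signals (2428 at an unadjusted p under 0.05), was also 0 under 10 of 18 alternatives, including the dyes as labelled (30 at an unadjusted p under 0.05) and the deposited values turned the same way (93), an alternative likewise added. It was 2003 in the deposited normalized values (1426 higher, 577 lower), 1975 in those values without centring (1807 and 168), 1426 with normexp (343 and 1083), 964 with normexp without an offset (355 and 609), 871 with a dye term (all higher) and 2216 with arrays scaled to equal SD (1731 and 485). Only replicate 3 had Cy3 as the higher dye, so the dye term cannot be told apart from a difference of that array. Leaving out 1 array gave 0 to 2899: 2899 without replicate 2, 276 without replicate 3 and 0 without replicate 1. Both normexp settings give more lower than higher windows and the others more higher than lower. The cause was not tested. With the dyes as labelled, replicate 2 opposes the other arrays and cancels part of their mean, so the counts under that direction carry little weight.

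X minus autosomes kept its direction and its unadjusted p under 0.05 under all 11 alternatives (0.15 to 0.54, the latter in SD units), and its p adjusted over 6 arms was under 0.05 in 3 of them. The common sign of the dyes as labelled was itself set from the peak list. Chromosome 4 minus autosomes, 0.39, was -0.019 with normexp and -0.017 with normexp without an offset, and 0.47 in the deposited values (adjusted p = 0.34); leaving out 1 array gave 0.21 to 0.60, with an adjusted p of 0.15 without replicate 1. The cause was not tested. X minus autosomal origins, -0.14, was -0.080 in the deposited values (permutation p = 0.20), 0.139 with normexp and 0.173 with normexp without an offset, and kept its direction and threshold under 6 others, among them -0.070 without replicate 1 and -0.23 without replicate 2; the cause was not tested. The ratio of observed to expected origins with a score at or above the median was 0.77 on 2L (adjusted p = 0.38) and 2.74 on chromosome 4 (adjusted p = 0.10), where the ratio hardly moved from 2.75 with fewer origins; X and 3R stayed past the threshold, and expected shares by probes changed no arm. Probes in origins minus outside was 1.44 in the deposited values, in another unit, and 0.26 with normexp, against 0.83. The mean r between arrays, 0.83, was 0.56 with either normexp setting (0.564 and 0.556), -0.23 with the dyes as labelled, by construction, and 0.72 to 0.89 with 1 array left out. Signal over background was lowest on replicate 1 in Cy5 (2.03).

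No paired analysis was possible because the series has 1 group. Counts of genes, gene lists, gene density and origins at gene starts were not run under any setting.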

Other observations

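The tests of the smaller range of replicate 2 and of the 90th against the 10th percentile on X were chosen only after the result was seen. Sequence assigned to heterochromatin and unplaced contigs differed between arrays. On replicate 1 alone, windows of YHet (14 windows), U (80) and 3RHet (67) had mean log2 ratios of 0.59, 0.48 and 0.23, while replicates 2 and 3 had -0.03 and -0.05, -0.03 and -0.05, and -0.07 and -0.15. Windows of 2LHet (8) had means of -0.21, 0.02 and -0.06 on replicates 1, 2 and 3, and those of XHet (11) 0.12, -0.04 and -0.01. The mean over windows of 2RHet and of 3LHet lay within 0.09 of 0 on each array. In the deposited values, 5 runs of at least 3 consecutive higher windows lay outside deposited origins, and all were on X, the highest from 13900001 to 13940000 at 0.35 ± 0.33 (SD, n = 3). The 5 longest runs of lower windows were all on 3L, between 370001 and 2370000, at mean log2 ratios of -0.22 to -0.28. Turned by channel number, the X run had 0.32 ± 0.37 and the 3L runs -0.19 to -0.24.

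The GC content of windows followed the log2 ratio on replicate 2 (Spearman rho 0.42 across windows, rotation p = 8.5e-05, the smallest possible, adjusted p = 1.1e-04), less on replicate 3 (0.11, adjusted p = 1.1e-04) and not past the threshold on replicate 1 (0.03, adjusted p = 0.18).

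X was higher than the large autosomal arms at the 10th percentile of windows (by 0.22, 0.04 and 0.10 on replicates 1, 2 and 3) as well as at the 90th (by 0.44, 0.13 and 0.48), and outside origins by 0.18, 0.04 and 0.09. After adjustment for GC content at least 0.977 of the difference was left on each array, which argues against GC content as the cause. A uniform shift of X between the channels would give equal differences at both percentiles. An unequal copy number would give such a shift, but one fixed in the cell line would cancel, because both channels came from that line. The difference at the 90th exceeded that at the 10th by at least 2.28 bootstrap SE (100 kb blocks) on each array. This argues against a uniform shift as the whole of the pattern, no more firmly than that margin, which is smallest on replicate 1. For the shift at low windows it stays open: the difference at the 10th percentile was 0.704 of the mean difference on replicate 1 and 0.453 on replicate 3, neither close to the whole of it nor a small part of it on all arrays. Because peaks were called on the same values, such a shift may also have brought X regions into the list that would otherwise have been missed, and no biological explanation was tested, since the design has 1 group.

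Chromosome 4 was high on replicates 1 and 3 and not on replicate 2, also outside origins (0.54 and 0.27 against -0.08), although replicate 2 separated origins from the rest of that chromosome by 0.24. The values argue against a smaller range of replicate 2 by 1 common factor as the cause. The difference of replicate 2 divided by its own contrast between probes in and outside origins was -0.0875, with a bootstrap SE of 0.130. That lay below a bound of 0.265, a fixed fraction of the mean ratio of the other arrays. With GC adjustment the ratio was 0.0273 against a bound of 0.267 (SE 0.127), with 0.602 and 0.464 on replicates 1 and 3. Each SE covers replicate 2 alone, not the ratios behind the bound, so the case against GC content is weak. With normexp, the mean difference was -0.019. That setting changed background correction and left out dye normalization together, so it cannot tell these apart. The bound for the range assumes 1 common factor, but replicate 2 shrank more where signal was lower. Around wide origins it had 0.46 more than 20 kb inside and 0.02 within 5 kb outside the edge, against 1.68 and 0.38 on replicate 1. A range that shrinks unevenly therefore stays open. The cause was not tested further. No biological explanation was tested.

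Replicate 2 ran against the other arrays when turned by channel number. A candidate explanation is that its channels are numbered the other way round in the labels. Single-dye signals adjusted for GC content were higher in origins by 0.206 (log2) in Cy5, labelled channel 1, and by -0.0483 in Cy3 on replicate 2. On replicate 1 the values were 1.28 in Cy5, labelled channel 2, and 0.0546 in Cy3. On replicate 3 they were 0.97 in Cy3, labelled channel 2, and -0.0239 in Cy5. These values are what such a numbering predicts, but the peak list was made from the same arrays, and the labels do not name the BrdU channel. On each array the signal rose mainly in the dye that the deposited values treat as enriched. With all arrays reversed, BrdU-enriched DNA would be the nearly flat dye in origins. The values argue against such a reversal, within a list made from the same arrays. The correlations between arrays do not use that list. Over windows, r by channel number was -0.72 between replicates 1 and 2 and -0.87 between replicates 2 and 3. These values argue against the numbered channels holding the same DNA on all 3 arrays.

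Turning the sign of whole arrays gives only 4 assignments, too few for a share under 0.05; the real one called 0 windows, the highest of the others called 0, and all 4 had as many.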
